A study of Homo sapiens with 2 samples.

How the data were processed

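RNA was measured in tumours of HT-29, an established human colon cancer cell line, that had been implanted under the skin of NOD SCID mice, a strain without T and B cells. The mice were female and 5 weeks old when obtained. They were reared for 2 weeks on normal food or on food without methionine, tryptophan and niacin, per the study's design text, which elsewhere gives the experiment's length as 3 weeks. There was 1 library for each diet, 2 in all. How many mice or tumours went into a library, and whether tumours were pooled, is not given in the sources used here. Libraries were made with a stranded mRNA kit, per the labels' protocols. RNA extraction is described with QIAzol in the labels' protocols and with an RNeasy kit in the design text.

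The deposited values are FPKM (fragments per kilobase of transcript and of sequencing depth) for 26255 gene symbols in each library, per the file headers. TopHat2 2.1.1, Bowtie2 2.2.8, SAMtools 0.1.18, Cuffdiff 2.2.1 and the human build hg19 are named in the submitters' processing notes, without the role of each. A step that removes reads of mouse cells, the strand setting and the annotation used are not given in the sources used here. Reads from mouse stroma that resemble human sequence could therefore add to the values, and a gene and its antisense partner, overlapping genes, and near-identical copies such as histone genes cannot be told apart with certainty.

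FPKM are not counts, and no count model was run. For each gene the log2 ratio was log2((depleted + 1)/(normal + 1)), with a pseudocount of 1 FPKM, which understates the difference of low genes. Genes with a mean of at least 1 FPKM over both libraries were kept, 12414 in all, and those with a ratio of at least 2-fold either way were counted. With 1 library per diet no difference has a replicate check, and no p-value is given. The comparison is between 2 libraries, and the diet cannot be separated from other differences between the tumours.

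Before the data were examined, 38 gene lists were fixed, 10 of them on pathways that the diet names and the others on wider programmes, cell types and sample state. Of the 833 list entries, 832 had a symbol in the files, some under an older symbol. A list with at least 3 measured members, as 34 had, was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart under percentile 2.5 or over percentile 97.5. If genes were independent, 1.7 of 34 lists would do so by chance. Genes of a pathway are regulated together, so more would.

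The genes named were set by a rule fixed before the data were examined. It took the 10 highest and 10 lowest log2 ratios at a mean of at least 5 FPKM, the 2 highest and 2 lowest members of each nutrient list, the highest and the lowest member of each other list, and NNMT, NAMPT, NAPRT, MAT2A, MTAP, MTR, CTH, CBS, IDO1, KYNU, WARS, ATF4, DDIT3, ASNS, TRIB3, CHAC1, SLC7A11, MKI67 and CD274 at any level. The first part of the rule named only genes of short RNAs. After the values were seen, 2 rules were added: the same ranking without genes of short RNAs, and, in each list other than the nutrient lists that stood apart (the early response genes included), up to 4 members with the largest ratio of either sign at a mean of at least 20 FPKM. Another 4 gene lists were also made after the values were seen and are reported only among the closing observations.

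Depth was estimated from the steps in low values. The value of 1 fragment was 1.04 times as high in the depleted-diet library as in the normal-diet library, from 2251 low genes of which 67.0% had a ratio of whole numbers within 0.1%, against 2.09% after the values were jittered. Genes with a single transcript in GENCODE release 29, which is on another build, gave about 7.39e+06 fragments for the normal diet and 7.02e+06 for the depleted diet. This estimate rests on 46 and 65 genes whose FPKM times length in nt lay between 100 and 170, a window chosen after the values were seen. Their SDs of 7.77 and 8.75 were below the 20.2 of an even spread, but a window placed elsewhere could move the estimate. For a transcript of 2 kb, counting alone then gives a standard error of the log2 ratio of 0.54 at 1 FPKM, 0.17 at 10 FPKM and 0.05 at 100 FPKM, before the pseudocount. Among 254 such genes with a mean of at least 5 FPKM, 34.3% lay beyond the 95% range of counting error, so counting error is a lower limit on the spread.

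The steps were tested on simulated data of 12414 genes, of which 200 differed. The 2-fold count recovered 98% of 100 genes with 8-fold differences and 93% of 100 genes with 2.83-fold differences. Of 400 unchanged lists of 20 genes, 5.75% stood apart, and all 200 lists raised by 0.2 on the log2 scale did. The simulation held counting error only. Alternatives covered the pseudocount, the filter, the scaling of the libraries, the fold, the bins and the mean in place of the median. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.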

Results

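The data were 2 RNA sequencing libraries from HT-29 tumours, 1 from the normal diet and 1 from the diet without methionine, tryptophan and niacin. FPKM were above 0 for 16481 genes on the normal diet and 16427 genes on the depleted diet. TMSB10 was the highest gene on the normal diet at 6077 FPKM, and RPL41 on the depleted diet at 5705 FPKM. The 10 highest genes held 8.40% and 8.17% of the summed FPKM. Over the 12414 genes with a mean of at least 1 FPKM, the median log2 ratio of depleted to normal was close to 0 and the quartiles were -0.13 and 0.13. No value below has a replicate, and each difference is one between 2 libraries.

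The first question was whether genes that handle the withdrawn nutrients differed between the diets. The design text names NNMT, the enzyme that methylates nicotinamide with S-adenosylmethionine, which is made from methionine. NNMT was 6.74 FPKM on the normal diet and 9.50 FPKM on the depleted diet, a log2 ratio of 0.44. For scale, the SD of the log2 ratio was 0.24 over the 2361 genes with a mean of 5 to 10 FPKM, short RNAs left out. MAT2A, which makes S-adenosylmethionine, was 159 and 184 FPKM (log2 ratio 0.21), and MTAP, which salvages methionine, was 29.9 and 35.5 FPKM (0.24). NAMPT, which makes NAD from nicotinamide, was lower on the depleted diet at 26.0 against 30.2 FPKM (-0.21). None of the 10 nutrient lists had a median that stood apart from matched random lists.

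In the methionine cycle list 7 of 12 measured members were higher and 5 lower on the depleted diet, with a median of 0.04 at percentile 78.9. Its highest ratios were AHCYL2 (0.33) and MTRR (0.23), and MTR, methionine synthase, was 6.88 and 6.64 FPKM. Of 16 members of methionine salvage and polyamine synthesis, 9 were higher, with a median of 0.04 at percentile 87.6. Among them AMD1, which supplies the aminopropyl donor of polyamines, was 51.5 and 62.8 FPKM (0.28), and SRM, spermidine synthase, 36.4 and 43.2 FPKM (0.24). The folate list had 9 of 15 members higher and a median of 0.03 at percentile 72.8. Its highest ratios were MTHFD2L, a mitochondrial enzyme (0.825 and 1.53 FPKM, 0.47), and SLC19A1, a folate carrier (6.72 and 8.68 FPKM, 0.33). The ratio of MTHFD2L is within counting error, which at 1 FPKM is 0.54 for a transcript of 2 kb. The lowest ratios of the folate list were MTHFD1L (22.1 and 16.7 FPKM, -0.39) and MTHFD2 (71.9 and 61.9 FPKM, -0.21), which are also mitochondrial. CTH, of transsulfuration, had a log2 ratio of -0.03, and CBS was under 0.2 FPKM in both libraries.

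Of 18 members of nicotinamide and NAD metabolism, 9 were higher and 9 lower, with a median of -0.01 at percentile 40.1. NNMT had the highest ratio, and NUDT12 (-0.38) and PARP2 (-0.37) the lowest. NAPRT, which makes NAD from nicotinic acid, was 100.1 and 96.0 FPKM. Of 13 members of tryptophan and kynurenine metabolism, 7 were higher, with a median of 0.07 at percentile 78.4. IDO1, the first enzyme of kynurenine synthesis, was at 0.367 and 0.229 FPKM, too low for a comparison at this depth, and KYNU was at 3.04 and 3.23 FPKM.

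The amino acid response, which ATF4 drives when amino acids are short, was not higher on the depleted diet. Of its 34 measured members 14 were higher and 20 lower, with a median of -0.04 at percentile 21.9. ATF4 was 266 and 246 FPKM (-0.11), TRIB3 50.2 and 42.3 FPKM (-0.24), and DDIT3, a stress transcription factor, 87.9 and 59.7 FPKM (-0.55). PPP1R15A (-0.70) and ATF3 (-0.62) had the lowest ratios, while ASNS, asparagine synthetase, was 35.5 and 39.4 FPKM (0.15). CHAC1 was 3.84 and 3.89 FPKM, and SLC7A11, the cystine transporter, 11.5 and 10.9 FPKM. With the mean in place of the median and genes of short RNAs left out, an alternative chosen after seeing the data, this list stood apart as lower, with a mean of -0.09 at percentile 1.85.

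Amino acid transporters were higher in 11 of 19 members (median 0.02, percentile 72.6), and cytosolic aminoacyl-tRNA synthetases in 9 of 20 (median -0.01, percentile 65.8). WARS, which charges tryptophan onto its tRNA, was 25.1 and 27.6 FPKM (0.13). DNA and histone methyltransferases were higher in 17 of 26 members, with a median of 0.08 at percentile 95.4. Of these DNMT1, the maintenance methyltransferase (15.7 and 19.1 FPKM, 0.26), and its partner UHRF1 (14.3 and 17.8 FPKM, 0.29) were higher. The de novo enzymes DNMT3B, at low values (2.75 and 1.63 FPKM, -0.51), and DNMT3A (9.82 and 8.21 FPKM, -0.23) were lower. Glutathione and NRF2 targets were higher in 8 of 22 members (median -0.06, percentile 19.3), with HMOX1 at 4.58 and 6.66 FPKM and OSGIN1 at 7.38 and 4.86 FPKM.

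The second question was which wider programmes differed. Hypoxia response genes were lower in all 19 measured members, with a median of -0.38, below each of the 10000 random lists. ADM, a vasodilator peptide, was 74.1 FPKM on the normal diet and 46.6 FPKM on the depleted diet (-0.66), NDRG1 1034 and 715 FPKM (-0.53), and PDK1, which limits pyruvate entry into mitochondria, 34.1 and 23.1 FPKM (-0.54). Glycolysis genes were lower in 15 of 19 members, with a median of -0.17 at percentile 0.01. ENO2 was 77.3 and 56.1 FPKM (-0.45), ALDOA 1374 and 1049 FPKM (-0.39), and PGK1 649 and 518 FPKM (-0.33).

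Chaperones were higher on the depleted diet. In the list of the unfolded protein response and heat shock, 22 of 23 members were higher, with a median of 0.23, above each of the 10000 random lists, but its mean was at percentile 95.4, within their range. HSPH1 was 37.4 and 69.9 FPKM (0.88), HSPA8 769 and 1118 FPKM (0.54), and HSPA5, the main chaperone of the endoplasmic reticulum, 149 and 191 FPKM (0.35). Intestinal stem cell and WNT targets were higher in 9 of 13 members, with a median of 0.28, also above each random list, but with a mean at percentile 96.5. The median was 0.14 without a filter on low values and 0.15 with a pseudocount of 5, and its bootstrap interval over members, -0.0044 to 0.38, included 0. The higher members included MYC at 76.1 and 106 FPKM (0.47), which was also in the early response list. CCND1, which encodes cyclin D1, was 32.8 and 43.0 FPKM (0.38), and SOX9 30.8 and 40.1 FPKM (0.37). The 4 lower members were NOTUM (-0.31), TCF7 (-0.27), AXIN2 (-0.04) and PROM1 (-0.004). Cholesterol synthesis genes were higher in 16 of 24 members, with a median of 0.08 at percentile 99.6 and a bootstrap interval of -0.04 to 0.13 that included 0, SQLE among them at 155 and 192 FPKM (0.30).

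Early response genes, fixed as a list of sample state because they react to handling of tissue, were also lower, in 12 of 16 members with a median of -0.21, below each random list. FOS was 60.6 and 37.1 FPKM (-0.69) and DUSP1 17.7 and 8.12 FPKM (-1.04). The p53 targets and growth arrest genes were lower in 14 of 18 members (median -0.18, percentile 0.05), with CDKN1A, a cell cycle inhibitor, at 32.6 and 21.6 FPKM (-0.57). Autophagy and lysosome genes were lower in 16 of 22 members (median -0.17, percentile 0.02), with MAP1LC3B at 30.3 and 22.5 FPKM (-0.41). Type I interferon genes were lower in 21 of 31 members (median -0.13, percentile 0.05), with OASL at 13.8 and 7.28 FPKM (-0.84) but IFITM1 higher (0.47). NF-kB cytokines and chemokines were lower in 12 of 15 members (median -0.13, percentile 2.11), with CXCL1, which attracts neutrophils, at 10.5 and 4.92 FPKM (-0.96). The early response list was the 1 list of cell type or sample state that stood apart, and it was lower in the same library as these lists, hypoxia and glycolysis.

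In all, 10 of the 24 other lists stood apart, 3 higher and 7 lower. The interferon list no longer stood apart at a mean of at least 5 FPKM (median -0.05, percentile 18.4), nor the NF-kB list with a pseudocount of 0.1 (percentile 2.85). With the mean of the members only 4 of the 10 stood apart, namely hypoxia, early response, p53 targets and interferon, so that none of the 3 higher lists did. The others lay at percentile 95.4 for the unfolded protein response and heat shock, 96.5 for WNT targets, 90.8 for cholesterol synthesis, 3.83 for glycolysis, 3.48 for autophagy and lysosome, and 2.95 for NF-kB. With genes of short RNAs also left out, an alternative chosen after seeing the data, 9 of the 10 stood apart and cholesterol synthesis (percentile 96.6) did not.

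**Figure D1:**
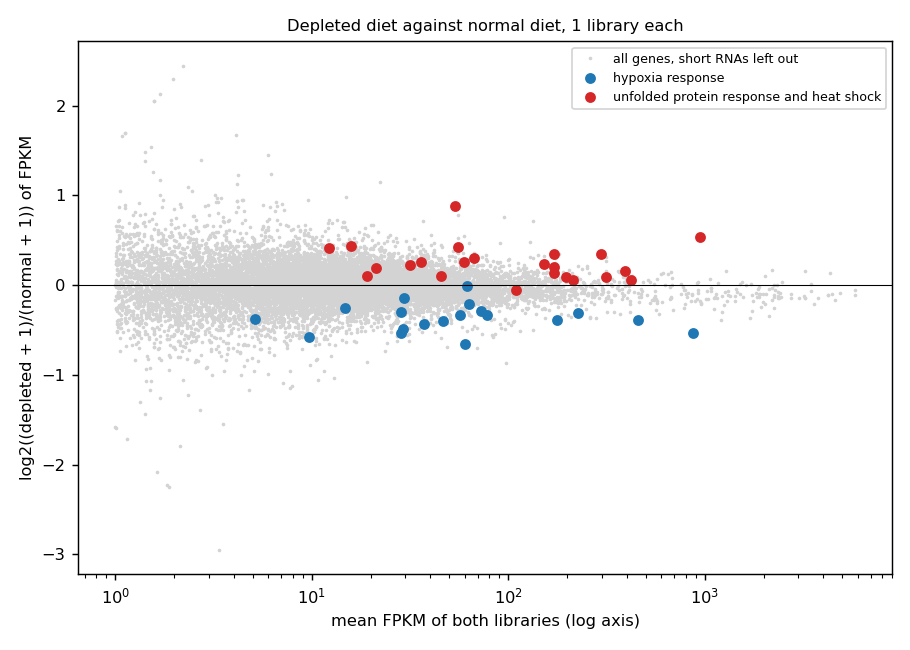
Log2 ratio of depleted to normal diet against mean FPKM (log axis) for each gene with a mean of at least 1 FPKM that is not a short RNA (grey), 1 library per diet. The 19 hypoxia genes (blue) lie below 0, and 22 of the 23 unfolded protein response and heat shock genes (red) lie above 0.

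Lists within the range of random lists included the cell cycle, with 21 of 36 members higher (median 0.05, percentile 94.9) and MKI67, a proliferation marker, at 39.9 and 44.5 FPKM (0.15). Antigen presentation (median -0.03, percentile 38.4) had 9 members higher and 9 lower, and immune ligands and checkpoints of tumour cells 6 higher and 8 lower (-0.05, percentile 21.9). CD274, which encodes PD-L1, was at 0.0809 and 0.265 FPKM, too low for a comparison at this depth. Fatty acid genes (-0.02, percentile 38.8), absorptive differentiation (-0.05, percentile 20.7), goblet and enteroendocrine differentiation (0.06, percentile 93.5) and epithelial-mesenchymal transition (-0.08, percentile 15.6) were also within it. Without a filter on low values, absorptive differentiation (percentile 1.43) and goblet and enteroendocrine differentiation (99.3) stood apart, the latter also with both libraries scaled to a common sum (99.8). Absorptive differentiation had 6 members higher and 11 lower. Its highest ratio was GUCA2A, a guanylin precursor, at 2.72 and 9.20 FPKM (1.45), while the related GUCA2B was lower (7.40 and 5.68 FPKM, -0.33). Its lowest ratio was CEACAM7, at low values (2.68 and 1.27 FPKM, -0.69).

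Markers of other cell types were few at 1 FPKM or more. Cells of the host are mouse cells, while the values are for human genes. The cell type lists therefore cannot tell how much of each host cell type the tumours held. Fibroblasts had 5 measured markers (median 0.18, percentile 89.4), endothelium 3 (0.05, percentile 62.8), macrophages and neutrophils 4 (0.23, percentile 96.5) and skeletal muscle 4 (-0.03, percentile 39.5). Adipocytes and epidermis had 2 each, lower in each case, and lymphocytes and erythroid cells 0. With a pseudocount of 0.1 the macrophage and neutrophil list stood apart as higher (percentile 98.3). Over its alternatives the percentile ran from 51.7 to 98.3 and the median from 0.0014 to 0.42. Its higher measured members were near 1 FPKM, CD14 (0.71 and 1.49 FPKM) and LAPTM5 (0.87 and 1.75 FPKM). Its lower ones were CD68 (25.6 and 20.8 FPKM) and LYZ (2107 and 1972 FPKM), and PTPRC, also on the list, was at 0.027 and 0 FPKM. Ribosomal protein genes (median -0.08, percentile 20.7), nuclear-encoded oxidative phosphorylation genes (-0.08, percentile 10.5) and housekeeping references (-0.11, percentile 4.06) were lower in most members but within the range of random lists. Housekeeping references lay just outside it with 10 bins (percentile 2.49) or with both libraries scaled to a common sum (percentile 2.48).

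Single genes with large ratios were few. At least 2-fold higher on the depleted diet were 65 genes, 40 of them short RNAs, and at least 2-fold lower 46 genes, 20 of them short RNAs. The 20 genes with the most extreme ratios were all short RNAs listed at 0 in one library, such as SNORD2 at 585 FPKM on the depleted diet and SNORD30 at 375 FPKM on the normal diet. Without short RNAs and at a mean of at least 5 FPKM, 3 genes were at least 2-fold higher and 5 lower, by the ranking added after the values were seen. The higher ones were GUCA2A, TNS4, a focal adhesion protein (13.4 and 31.0 FPKM, 1.15), and the antisense transcript ZNF32-AS1. The lower ones were LGALS1, which encodes galectin-1 (11.1 and 4.45 FPKM, -1.15), TOPORS-AS1, the histone gene HIST2H2BC, PPP1R14D (14.9 and 6.64 FPKM, -1.06) and DUSP1.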

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

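Leaving out short RNAs or shared members, and the mean of members without short RNAs, were chosen after seeing the data; the other alternatives were fixed before. No paired analysis was possible because each diet has 1 library, and no replicate could be left out. The nutrient lists kept their side of the threshold in 119 of 120 values; the amino acid response had a mean of -0.0896, standing apart as lower, with the mean of members and short RNAs left out, and the cause was not tested. Against 65 genes at least 2-fold higher and 46 lower, there were 124 and 93 with a pseudocount of 0.1, 35 and 20 with 5, 40 and 23 at a mean of at least 5 FPKM, 121 and 79 with both libraries scaled to a common sum, 205 and 189 at 1.5-fold, and 25 and 26 without short RNAs. Without a filter 72 were lower, and at 3-fold 28 were lower. A smaller pseudocount, a lower fold, larger values or no filter let more genes pass by construction, and the opposite choices fewer. The number of other lists standing apart was 4 in place of 10 with the mean of members and 9 once short RNAs were also left out, so short RNAs among the random lists account for most of that loss. In its other alternatives it was 9 to 13. Medians of the other lists gave 269 values on the same side, 9 weaker and 6 stronger. For named genes, 290 values kept their side of 2-fold and 14 passed it, with none reversed. Counting error limits ratios near 1 FPKM most.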

Other observations

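All tests in this part were chosen after the values were seen, and 38 families of gene names had also been looked at. The 4 gene lists made then are not independent of the data, so each is given again without the members, or families, already seen. Families were left out only after a first run that left out single genes already seen, which gave medians of -0.22 for 15 further hypoxia targets and 0.11 for 22 ribosome biogenesis genes. Further hypoxia targets outside the fixed list were lower in 20 of 20 measured genes (median -0.26), and in 12 of the 12 not seen before. Cytosolic chaperones and their partners were higher in 22 of 23 (median 0.21), and in 8 of the 8 not seen before, with a median of 0.17 at percentile 99.9. CHORDC1, a partner of HSP90, was 9.70 FPKM on the normal diet and 20.2 FPKM on the depleted diet. Endoplasmic reticulum chaperones were higher in 18 of 18 (median 0.21), but 13 of them were in the fixed lists, and the 3 not seen before had a median of 0.04 at percentile 80.03, within the range of random lists. With the mean in place of the median, the full cytosolic list was at percentile 97.2 and the full endoplasmic reticulum list at 95.9, both within the range of random lists.

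Ribosome biogenesis genes were higher in 23 of 29 (median 0.16), and MYC, which drives them, was higher too. With the mean in place of the median the list was at percentile 94.4, within the range of random lists. It stood apart in 11 of 12 alternatives, the mean with short RNAs also left out among them. A hypothesis is that these genes may be higher along with MYC. In the 14 not seen before, 11 were higher, with a median of 0.14 against a central 95% of -0.12 to 0.07 for random lists. This median shows only that these genes were higher. With 1 library per diet it cannot bear on a link between MYC and these genes, which was not tested.

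The first pattern weighed is the lower hypoxia list. Scaling between the libraries would move all genes alike. It is argued against by the median of -0.0029 over all genes with a mean of at least 1 FPKM. The hypoxia median lay -0.28 from the housekeeping median (bootstrap 95% interval over members -0.34 to -0.18). Housekeeping references lay within the range of random lists, so this difference largely repeats the comparison that found the pattern and is no separate test. The matched random lists, by which the pattern was found, add nothing further on expression level. Medians of all genes in bands of expression repeat that matching more coarsely and are no separate test of a trend with level. The lowest was -0.059, above the bootstrap interval of the hypoxia median (-0.43 to -0.30). A chance choice of listed genes is argued against by the 12 targets not seen before, with a median of -0.23 against -0.12 to 0.12 for random lists. A difference between single tumours unrelated to diet, such as size, cannot be told apart from the diet, because there is 1 library per diet. A lower hypoxia response on the depleted diet stays a hypothesis.

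The second pattern is that chaperones were higher while early response genes were lower. The early response median was -0.21 (bootstrap 95% interval over members -0.56 to -0.02) and the chaperone median 0.23. These opposite signs are the pattern itself, so they do not decide whether a handling stress had a part in it, and handling stays open. A difference between single tumours unrelated to diet cannot be told apart from the diet, with 1 library per diet.

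The third pattern is short RNAs that are listed at 0 in one library and high in the other, 51 of the 85 with a mean of at least 1 FPKM. A candidate explanation is a few fragments divided by a short length. Among 36 values of short RNAs sharing a length with another in the same library, 77.8% were whole multiples of the smallest value at that length within 1%, against a median of 17.1% and a highest value of 36.4% in 100 shuffles of the lengths. The 36 values were not limited to the short RNAs listed at 0 in one library. Fragments divided by a length give whole multiples at any number of fragments. The share therefore cannot show that the fragments were few. No biological explanation of the short RNA values was tested.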
